A study of Homo sapiens with 9 samples.

How the data were processed

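Expression was measured in PBMC of 3 human donors, 1 sample per donor and delay (no delay, 2 h and 4 h), on 9 one-colour arrays with 54675 Affymetrix probe sets. Per the labels' protocols, blood was separated over Ficoll, samples were kept frozen in Trizol and the RNA was labelled with NuGEN Ovation. RMA, which corrects background, normalizes arrays by quantiles and summarises probes per probe set, is named in the submitters' processing notes without a version. The labels give each sample's delay and donor, so samples of one donor are paired by the labels.

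The deposited table holds natural log values with 1 column per array. In 100% of probe sets the median of the 3 no-delay arrays was 0 within 3e-07, so each value is the natural log of the ratio of a probe set's signal to its median without delay. Values ran from -4.61 to 4.98, and 4 stood at the lowest value, the natural log of 0.01. The step that made these ratios is not given in the sources used here. They were divided by the natural log of 2 to give log2 units, in which the medians of the 9 arrays lay between -0.02 and 0.01. Differences between delays within a probe set are unaffected by this centring. The signal itself cannot be recovered, so nothing could be said of brightness or of signal over background. No values were missing and no column was left unmapped.

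Probe sets were named from the platform's annotation, with symbols checked through gene IDs against RefSeq names (assembly GRCh38.p14; 41037 of 41091 matched, 0 renamed). In the table, 41091 probe sets had 1 symbol, 1801 several and 11721 none, and 62 were controls. Only those with 1 symbol were tested, as 1 probe set per gene, and Y-linked genes, XIST and TSIX were left out of all tables, leaving 19740 genes. The design fixed before the data were examined had a filter on dim probe sets and took the brightest probe set of each gene. Both need signal levels, so no filter was used and the probe set with the largest SD within donors over the 9 arrays was taken. Delay labels were not used, but arrays of 1 donor differ in delay, so this SD holds the change with delay. The choice therefore favours probe sets that change with delay and can enlarge the changes given. Alternatives to it are given with the other settings.

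limma 3.58.1 in R 4.3.3 fitted delay and donor to all 9 arrays (lmFit and eBayes with default prior, 4 residual degrees of freedom, prior degrees of freedom 4.39). Adjusted p-values are limma's with the Benjamini-Hochberg method over the genes tested, two-sided, with a threshold of 0.05. Contrasts were 4 h and 2 h against no delay, 4 h against 2 h, the departure from a straight line and a moderated F over the 3 times. The check of the pairing was mixed: after removal of the delay means, the correlation over genes averaged 0.27 within donors (-0.21 to 0.56, 9 pairs) and -0.14 between donors (-0.43 to 0.36, 18 pairs), while the consensus correlation within donors from limma's duplicateCorrelation was -0.0072. Since the labels give the pairing, the donor block was the main setting whatever this check showed.

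The 27 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Camera compares a list with all other genes, and fry asks whether its genes move, on balance, one way. Lists overlap: NR4A2, for example, is in the immediate early and the cAMP lists. Named genes were also chosen by a rule fixed before the data were examined. It took up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold that moved the same way in 3 of 3 donors for 4 h against no delay, and 8 each way for 2 h. For 4 h against 2 h, where no gene passed, it took the 3 smallest p each way, and from each list up to 4 members with the smallest p at 4 h. Genes of the HLA, KIR, immunoglobulin and T cell receptor families and genes known for common deletions were left out of the naming. Other genes are marked as named after their values were seen.

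The procedure was tested on simulated data with the residual spread of these arrays and 19740 genes. For 4 h against no delay it recovered 10.4% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 93.9% of those changed 4-fold, and 0.89% of its calls were unchanged genes. For 2 h against no delay, where the simulated changes were smaller than at 4 h, it recovered 0%, 0% and 36.4% of the same genes. In 20 runs without any change it made 0 calls. Shared no-delay arrays were simulated in 50 runs, in which the genes of smallest p, as many as were called, were compared between delays. All these runs drew independent noise with the same SD in every array, and all probe sets of a changed gene moved alike. A noisier array, correlation between genes and disagreeing probe sets were not simulated, so the rates may not hold for the real arrays.

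Alternatives were the donor left out or as a random effect, each array centred on its median, the mean of a gene's probe sets, every probe set on its own, array quality weights, the 6 arrays of a comparison alone, an adjusted p of 0.1, a minimum of 1.5-fold, and each array and each donor left out in turn. Chosen after seeing the data were the probe set by type and ID, genes at or above the median SD within donors, a robust prior, the gene lists without the no-delay array of donor 1, and the lists with the other choices of probe set. Figures were drawn with matplotlib 3.10.9.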

Results

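The series asked whether short delays before processing change gene expression in peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes that stay at the interface when blood is centrifuged over Ficoll. Each of 3 donors gave 3 samples, processed with no delay, after 2 h or after 4 h, and RNA from each of the 9 samples was hybridised to 1 array. The numbering of the donors is arbitrary. The deposited values covered 54675 probe sets, of which 41091 carried 1 gene symbol, and 19740 genes were tested. Values were ratios to the median of the 3 no-delay arrays, so each gene was compared with itself across delays and no absolute level was available. The number of arrays set the precision, with a median standard error of 0.16 log2 for a difference between 2 delays. All changes below are log2 differences between delays within donors, ± SE from limma with the donor as a block (n = 3 donors).

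After 4 h the largest rise was that of NR4A2, an orphan nuclear receptor of the immediate early class, which was 8.81-fold higher than without delay (3.14 ± 0.17, adjusted p = 0.00049). The bZIP factor MAFF was 7.05-fold higher (2.82 ± 0.30, adjusted p = 0.0040), the prostaglandin E receptor PTGER3 6.44-fold (2.69 ± 0.23) and ID1, an inhibitor of basic helix-loop-helix factors, 5.85-fold (2.55 ± 0.15). PFKFB3, which makes the allosteric activator of phosphofructokinase, the salt-inducible kinase SIK1 and the zinc finger gene ZBTB10 rose by 2.54 ± 0.17, 2.54 ± 0.18 and 2.53 ± 0.34. The EGF receptor ligand HBEGF rose by 2.52 ± 0.14, and NAMPT, the rate-limiting enzyme of NAD salvage, by 2.49 ± 0.16. The cAMP-responsive modulator CREM rose by 2.38 ± 0.23, the lipolysis inhibitor G0S2 by 2.36 ± 0.15 and the ethanolamine kinase ETNK1 by 2.35 ± 0.20. Each of these 12 genes was higher in 3 of 3 donors, which the rule for naming required. The ETNK1 value belongs to the probe set chosen for it, since the one chosen by probe set type and ID gave -0.12. PTGER3, SIK1 and HBEGF rose at an unadjusted p under 0.05 in 4 of 10, 1 of 2 and 2 of 4 probe sets (lowest -0.07, 0.03 and -0.29). ZBTB10 kept its call in 7 of 9 fits that left out 1 array each, and the other 11 in all 9.

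Falls after 4 h were smaller. SOS1, a Ras exchange factor, was lowest at -1.53 ± 0.27 (adjusted p = 0.029), followed by GIMAP8 at -1.49 ± 0.13 (adjusted p = 0.0018), ZNF226 at -1.44 ± 0.23 and the histone H4 lysine methyltransferase KMT5B at -1.42 ± 0.15. The fractalkine receptor CX3CR1, found on non-classical monocytes and cytotoxic lymphocytes, fell by 1.41 ± 0.16 and CCR2, the receptor that classical monocytes use to follow CCL2, fell by 1.39 ± 0.28 (adjusted p = 0.046). NAPEPLD, PAQR8, YIPF5 and DIDO1 changed by -1.39 ± 0.18, -1.29 ± 0.15, -1.21 ± 0.15 and -1.21 ± 0.17. GIMAP6 and GIMAP4, which like GIMAP8 encode GTPases expressed mainly in lymphocytes, changed by -1.23 ± 0.12 and -1.19 ± 0.14. All 12 were lower in 3 of 3 donors, again by the rule for naming. The calls of SOS1, ZNF226 and CCR2 held in 3, 4 and 2 of the 9 fits that left out 1 array each, while those of GIMAP8, KMT5B, GIMAP6 and GIMAP4 held in all 9. The probe set of YIPF5 chosen by type and ID gave 0.04. SOS1, KMT5B and CX3CR1 fell at an unadjusted p under 0.05 in 2 of 5, 2 of 3 and 1 of 2 probe sets (highest -0.004, 0.15 and -0.44). Of 4 probe sets of DIDO1, 2 fell and 2 rose at an unadjusted p under 0.05 (highest 0.41), and of 4 of ZNF226, 1 fell and 1 rose (0.52), so the probe sets of these 2 genes disagree.

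**Figure D1:**
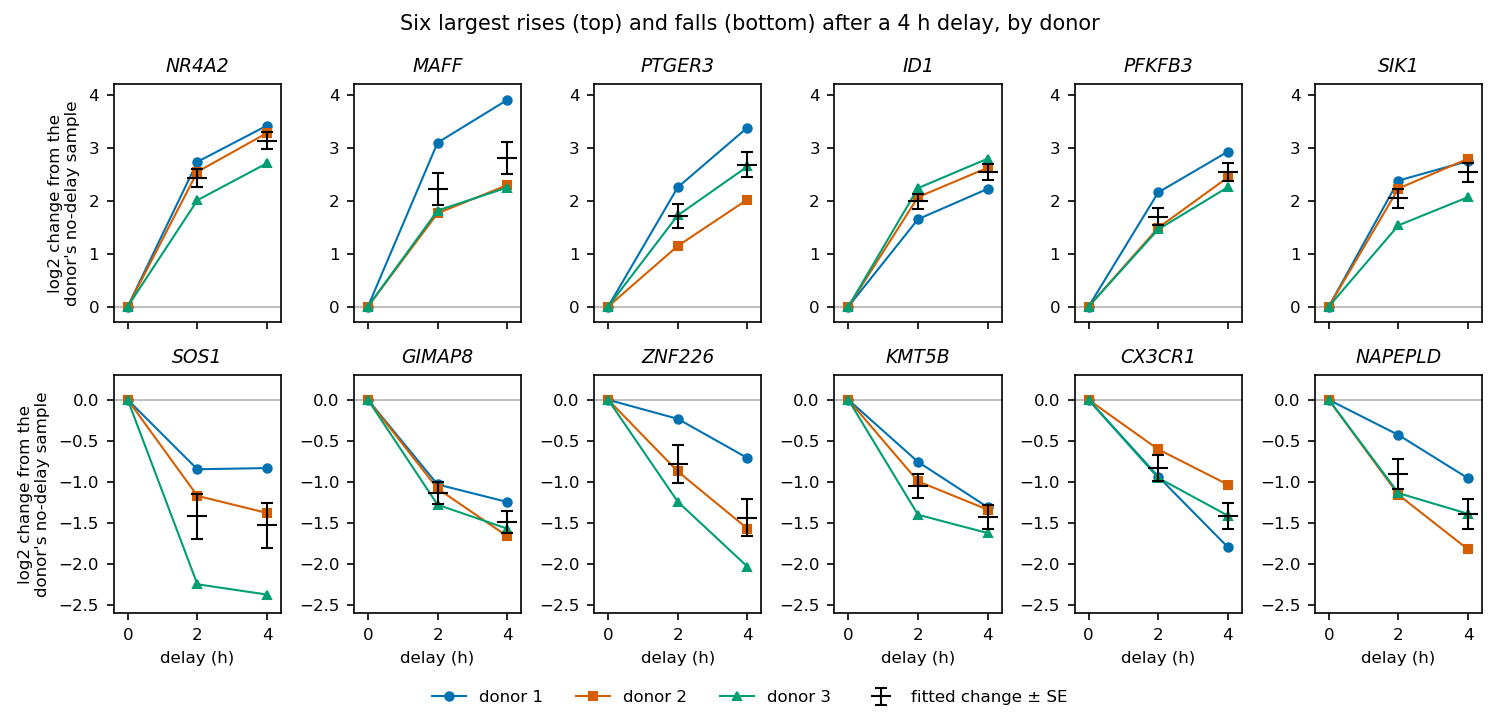
Log2 change from the same donor's no-delay sample (vertical axis) against delay in hours (horizontal axis) for the 6 largest rises (top) and 6 largest falls (bottom) after 4 h; coloured lines are the 3 donors and black bars the fitted change ± SE. NR4A2 reaches 3.14 and SOS1 -1.53 after 4 h, and every line of the 12 genes ends on the side of the fitted change, which their choice required.

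In all, 491 of 19740 genes passed an adjusted p of 0.05 for 4 h against no delay: 370 rose and 121 fell, so that 75.4% of the calls were rises. Among them 191 rose and 32 fell by at least 2-fold, and all 491 moved the same way in 3 of 3 donors. The median called rise was 1.01 and the median called fall -0.83, while the median over all genes was -0.05. The count depended on every array. Without the no-delay array of donor 1 it was 1349, of which 637 rose and 712 fell (47.2% rises), and it contained all 491. Without the no-delay array of donor 2 or 3 it was 201 or 294; without the 2 h array of donor 1, 2 or 3 it was 220, 176 or 174; and without the 4 h array of donor 1, 2 or 3 it was 241, 113 or 60. Without all arrays of donor 1, 2 or 3 it was 1332, 0 or 11. A fit to the 6 arrays of these delays alone called 47 genes. The median residual SD over genes was 0.19 log2 with all arrays and 0.13 without the no-delay array of donor 1.

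**Figure D2:**
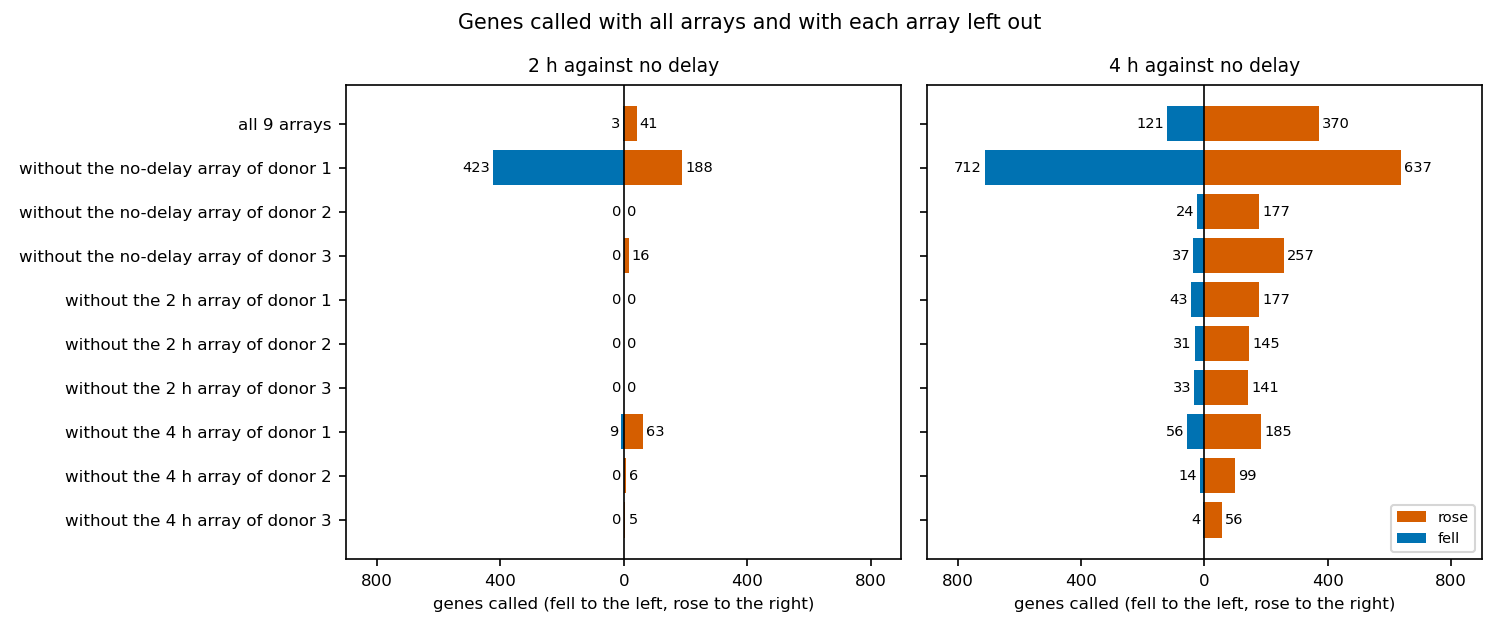
Number of genes called (horizontal axis, rises to the right and falls to the left of 0) with all 9 arrays and with each array left out (vertical axis), for 2 h (left) and 4 h (right) against no delay. Leaving out the no-delay array of donor 1 raises the 4 h count from 370 rises and 121 falls to 637 and 712; leaving out any other array lowers it.

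Immediate early genes, which are transcribed within minutes of many stimuli without new protein synthesis, were the list with most calls. Of 32 measured, 19 rose and 1 fell after 4 h (28 and 1 adjusted over the list alone), and their median change was 0.89. Beside NR4A2 and MAFF, the AP-1 subunits FOSL2 and JUN rose by 2.15 ± 0.18 and 2.09 ± 0.18 and the Krüppel-like factor KLF10 by 1.33 ± 0.12. The member that fell was MYC, at -0.72 ± 0.14 (adjusted p = 0.043), a call that held in 1 of 9 fits without 1 array. Of 22 NF-kB target and feedback genes 7 rose and none fell (14 and 0 adjusted over the list alone; median 0.44). They included the inhibitors TNFAIP3 (1.68 ± 0.15) and NFKBIA (1.12 ± 0.12), the dendritic cell and activation marker CD83 (1.80 ± 0.18) and the survival gene BCL2A1 (1.01 ± 0.12). Of 2 probe sets of NFKBIA, 1 rose at an unadjusted p under 0.05 and the other read 0.06. Of 33 cytokines, chemokines and growth factors, 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.24). HBEGF, the neutrophil chemokine CXCL8 (2.02 ± 0.15), VEGFA (1.79 ± 0.17) and OSM (1.19 ± 0.12) rose, and TNFSF14, named after its value was seen, fell (-1.001 ± 0.13). These 3 lists stood above other genes by camera with its preset correlation (adjusted p = 2.47e-27, 1.60e-08 and 2.81e-05). None passed with an estimated correlation (adjusted p = 0.059, 0.13 and 0.063). The NF-kB and cytokine medians were 0.28 and 0.16 without the no-delay array of donor 1.

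Genes responsive to cAMP and CREB rose in 9 of 17 (13 adjusted over the list alone) with none fallen, and had the highest median of the 27 lists, 1.02. They included NR4A2, SIK1 and CREM and the cAMP phosphodiesterase PDE4D (1.69 ± 0.17). Of 18 glucocorticoid responsive genes 6 rose (11 adjusted over the list alone; median 0.64), among them KLF9 (1.76 ± 0.15), the insulin receptor substrate IRS2 (1.12 ± 0.13) and the mTORC1 inhibitor DDIT4 (0.95 ± 0.13). KLF9 read -0.23 with the probe set chosen by type and ID. Of 34 targets of hypoxia-inducible factor 8 rose (15 adjusted over the list alone; median 0.33), including PFKFB3, VEGFA, DDIT4 and the glucose transporter SLC2A3 (1.46 ± 0.14). None of 18 glycolysis enzymes passed (0 adjusted over the list alone); ALDOA stood at 0.42 ± 0.14 and HK2 at -0.47 ± 0.18. Of 16 circadian clock genes 3 rose (5 adjusted over the list alone; median 0.06, mean 0.36): NFIL3 by 1.64 ± 0.12, BHLHE40 by 1.04 ± 0.17 and PER3 by 0.93 ± 0.19. NFIL3 and BHLHE40 are also induced by many stimuli outside the clock, and PER3 read -0.20 with the other choice of probe set. The cAMP, glucocorticoid, hypoxia and clock lists passed camera with the preset correlation (adjusted p = 5.95e-16, 3.62e-07, 3.29e-09 and 0.0021), and none did with an estimated correlation (adjusted p = 0.059, 0.10, 0.10 and 0.11). The clock median was 0.21 and the glucocorticoid median 0.44 without the no-delay array of donor 1. Glycolysis passed neither (adjusted p = 0.16 and 0.59 with an estimated correlation).

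Of 28 genes of the unfolded protein and integrated stress response, 5 rose (8 adjusted over the list alone; median 0.14). They were CEBPB (0.90 ± 0.12), the chaperone DNAJB9 (1.39 ± 0.20), HERPUD1 (0.94 ± 0.17), DDIT3 (1.17 ± 0.24) and, named after its value was seen, PPP1R15A (1.23). Of 27 p53 target and apoptosis genes 4 rose (8 rose and 2 fell adjusted over the list alone, median 0.26). They were the BH3-only gene PMAIP1 (1.75 ± 0.16), PLK3 (1.31 ± 0.15), the cell cycle inhibitor CDKN1A (1.09 ± 0.14) and PLK2 (0.67 ± 0.13). PLK3 rose at an unadjusted p under 0.05 in 1 of 3 probe sets (lowest -0.11). NRF2 and oxidative stress genes rose in 2 of 25 (3 rose and 1 fell adjusted over the list alone; median 0.13), NFE2L2 itself (0.86 ± 0.16) and HMOX1 (0.71 ± 0.14). Of 20 heat shock proteins and chaperones only DNAJB1 rose (1.05 ± 0.16; 2 rose and 3 fell adjusted over the list alone; median -0.06), with HSPH1 at -0.72 ± 0.17 and not passing. The first 3 of these lists passed camera with the preset correlation (adjusted p = 0.00037, 1.81e-05 and 0.028) and none with an estimated correlation (adjusted p = 0.13, 0.18 and 0.55), and the heat shock list passed neither (adjusted p = 0.94 and 0.93 with an estimated correlation). The calls of NFE2L2 and HMOX1 each held in 1 of the 9 fits that left out 1 array, and the NRF2 list no longer passed without the no-delay array of donor 1 (adjusted p = 0.34). The median of the unfolded protein list fell to 0.03 and that of the p53 list to 0.12 without that array, with 1 and 2 members fallen.

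RNA splicing factors rose in 7 of 39 (22 adjusted over the list alone; median 0.58), including SON (1.12 ± 0.15), the SR protein kinase CLK1 (0.90 ± 0.14), HNRNPA1 (1.10 ± 0.19) and TRA2B (0.68 ± 0.13). The rise of SON is that of 1 of its 5 probe sets, since 2 others fell at an unadjusted p under 0.05 (lowest -0.46). The median of the list was 1.16 in donor 1, against 0.39 and 0.29 in donors 2 and 3. Of 68 oxidative phosphorylation subunits 3 rose (3 adjusted over the list alone; median 0.18): COX4I1 by 1.37 ± 0.12, NDUFB4 by 0.92 ± 0.13 and NDUFA5 by 0.80 ± 0.16. Of 53 cytosolic ribosomal proteins RPL37A alone rose (0.71 ± 0.15, 0 adjusted over the list alone, median 0.10). COX4I1, NDUFB4 and RPL37A rose at an unadjusted p under 0.05 in 1 of 4, 1 of 2 and 1 of 3 probe sets (lowest -0.22, 0.10 and 0.03). Camera with the preset correlation passed these 3 lists (adjusted p = 5.95e-16, 1.22e-06 and 0.0021), and with an estimated correlation none (adjusted p = 0.19, 0.58 and 0.59). Of the 3, the splicing list passed without the no-delay array of donor 1 (adjusted p = 9.51e-10), and the oxidative phosphorylation and ribosomal lists did not (adjusted p = 0.057 and 0.28); the 3 medians were then lower, at 0.35, 0.09 and 0.03.

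Lists of markers of the cell types in the preparation had medians between -0.07 and 0.16. Among 24 T cell markers 1 fell, the adaptor SIT1 at -0.72 ± 0.12 (2 rose and 5 fell adjusted over the list alone; median -0.07), with CD2 at -0.55 ± 0.12 and not passing. Among 23 B cell markers 3 fell (0 rose and 4 fell adjusted over the list alone, median 0.01, mean -0.09). They were CD24 at -1.14 ± 0.15, TCL1A at -0.59 ± 0.12 and SPIB at -0.62 ± 0.13. Of 2 probe sets of SPIB, 1 fell at an unadjusted p under 0.05 and the other read -0.04. CX3CR1 was the member that fell of 19 NK cell markers (0 rose and 1 fell adjusted over the list alone; median 0.07, mean -0.04, while GZMB stood at 0.26 ± 0.12) and CCR2 that of 26 monocyte markers (0 rose and 1 fell adjusted over the list alone; median 0.16, with MNDA at -0.53 ± 0.14). No dendritic cell marker of 16 passed (0 adjusted over the list alone; median 0.07; FCER1A 0.30 ± 0.13). None of the 5 lists passed camera (adjusted p = 0.29, 0.30, 0.88, 0.16 and 0.60; with an estimated correlation 0.71, 0.70, 0.93, 0.61 and 0.67). Without the no-delay array of donor 1, 5 T cell and 4 B cell markers fell and both lists passed camera as lower (adjusted p = 0.022 and 0.0057), with adjusted p = 0.53 and 0.27 with an estimated correlation.

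Lists of neutrophil, platelet, erythroid and basophil markers stand for cells outside the lymphocytes and monocytes. Over 30 neutrophil markers the median change was -0.03, and the chemokine receptor CXCR2 was the member that fell (-0.65 ± 0.11; 0 rose and 2 fell adjusted over the list alone). None of 28 platelet markers passed (0 adjusted over the list alone), with a median of -0.17 and TUBB1 at -0.58 ± 0.16 and PF4 at -0.46 ± 0.15. Camera with the preset correlation put the platelet list below other genes (adjusted p = 0.0064), which an estimated correlation did not (adjusted p = 0.61). The platelet median was 0.29 in donor 1 and -0.39 and -0.51 in donors 2 and 3, and without the no-delay array of donor 1, 5 platelet markers fell and the median was -0.40. No erythroid marker of 21 passed (0 rose and 1 fell adjusted over the list alone, median -0.10, BCL2L1 -0.60 ± 0.13). Without the no-delay array of donor 1, 2 erythroid markers fell and the median of the list was -0.02. Of 14 basophil and eosinophil markers GCSAML rose (1.89 ± 0.16; 3 adjusted over the list alone; median 0.00), with HDC, which makes histamine, at 0.55 ± 0.12 and not passing. The neutrophil, erythroid and basophil lists did not pass camera (adjusted p = 0.88, 0.26 and 0.20, and with an estimated correlation 0.93, 0.61 and 0.46). The basophil and eosinophil list did pass fry as higher (adjusted p = 0.028). The signal of 3 prime over 5 prime probe sets of beta-actin and GAPDH, which rises as RNA breaks down, changed by 0.01 ± 0.10 (SE over 3 donors) from no delay to 4 h.

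Of 33 interferon stimulated genes none rose and 2 fell, RIGI by 0.96 ± 0.17 and IFIT1 by 0.75 ± 0.15 (2 rose and 5 fell adjusted over the list alone; median -0.04). Among 20 T cell activation genes 3 rose and 1 fell (6 and 3 adjusted over the list alone; median 0.10): the early marker CD69 (1.16 ± 0.16), the phosphatase DUSP2 (0.94 ± 0.14) and the checkpoint receptor CTLA4 (0.80 ± 0.14) rose and MYC fell. No proliferation gene of 30 passed (0 adjusted over the list alone; median -0.06; MCM3 -0.46 ± 0.12). Camera passed none of these 3 lists (adjusted p = 0.30, 0.16 and 0.38; with an estimated correlation 0.63, 0.58 and 0.58). Without the no-delay array of donor 1 the interferon list passed as lower, with 1 risen and 5 fallen (adjusted p = 0.022), and not with an estimated correlation (adjusted p = 0.18); of the T cell activation genes 4 then rose and 3 fell, with a median of 0.17. Of the 75 called at 4 h among the genes named by the rule fixed before the data were examined, 31 kept the call in all 9 fits that left out 1 array and 45 in at least 7, and all 75 kept their direction in all 9. Beside those given above, BHLHE40, DNAJB1, CLK1, HNRNPA1 and RIGI kept it in 3, HERPUD1, DDIT3, NDUFA5, TRA2B, SIT1 and CTLA4 in 2, and PER3, PLK2, RPL37A, TCL1A, SPIB, CXCR2, IFIT1 and POLH in 1.

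**Figure D3:**
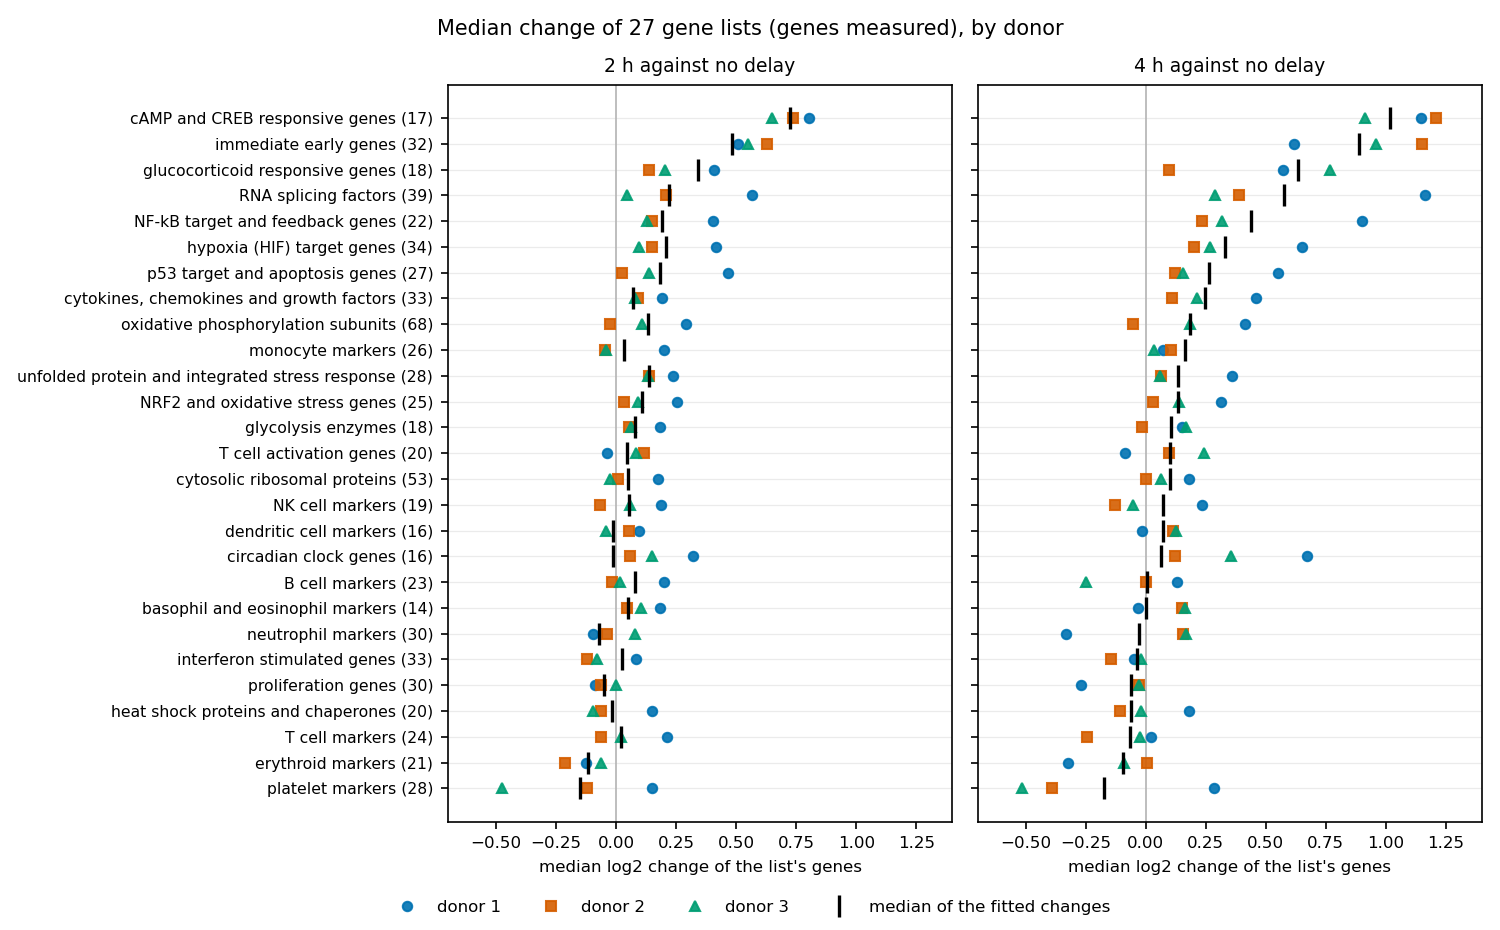
Median log2 change (horizontal axis) of the measured genes of 27 lists (vertical axis, number of genes in brackets) for 2 h (left) and 4 h (right) against no delay; coloured points are the 3 donors and black ticks the median of the fitted changes. The cAMP and CREB list is highest at 4 h with 1.02 and the platelet list lowest with -0.17, and the splicing list has donor 1 at 1.16 apart from 0.39 and 0.29.

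After 2 h NR4A2 again showed the largest rise. It was 5.40-fold higher (2.43 ± 0.17, adjusted p = 0.0055). MAFF rose by 2.23 ± 0.30, SIK1 by 2.05 ± 0.18, ID1 by 1.99 ± 0.15 and G0S2 by 1.91 ± 0.15. CREM rose by 1.79 ± 0.23, PTGER3 by 1.71 ± 0.23 and PFKFB3 by 1.70 ± 0.17. By the rule for naming, each rose in 3 of 3 donors. The falls were GIMAP8 (-1.13 ± 0.13, adjusted p = 0.022), KMT5B (-1.05 ± 0.15) and DUSP6, a phosphatase that switches off ERK (-1.04 ± 0.14). In all 44 genes were called, 41 up and 3 down. Immediate early genes rose in 7 of 32 (20 rose and 1 fell adjusted over the list alone), cAMP and CREB genes in 3 of 17 (10) and glucocorticoid genes in 3 of 18 (6). Cytokines rose in 3 of 33 (6 rose and 1 fell), NF-kB genes in 2 of 22 (6) and hypoxia genes in 2 of 34 (6). Without the no-delay array of donor 1, in the same order, 15, 8, 6, 5, 4 and 6 rose and 0, 1, 1, 2, 1 and 0 fell. COX4I1, NFIL3 and GCSAML were the called members of the oxidative phosphorylation, clock and basophil lists (1.08 ± 0.12, 1.02 ± 0.12 and 1.36 ± 0.16), and the other 18 lists had no call. Camera passed 14 lists with the preset correlation, 12 as higher and 2, the platelet (median -0.15, adjusted p = 0.0054) and erythroid markers (median -0.12, adjusted p = 0.029), as lower. With an estimated correlation it passed 0; immediate early genes had adjusted p = 0.055 and the platelet and erythroid markers 0.64 and 0.41. Of the 14, the immediate early, cAMP, glucocorticoid, hypoxia and platelet lists passed without the no-delay array of donor 1, the platelet list with a median of -0.31 and 2 members fallen.

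The 2 h count rested on single arrays even more. It was 611 (188 up, 423 down) without the no-delay array of donor 1 and 72 without the 4 h array of donor 1. It was 0 without the no-delay array of donor 2 or without the 2 h array of any donor, 16 without the no-delay array of donor 3, and 6 and 5 without the 4 h arrays of donors 2 and 3. Without all arrays of donor 1 it was 471, and 0 without those of donor 2 or 3. At an unadjusted p under 0.05, 1305 genes passed in the fit to all arrays. The 6 arrays of these delays alone called 4 genes.

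Of the 41 genes risen at 2 h, 40 were also called as risen at 4 h, and the 3 that fell at 2 h had all fallen at 4 h. Independent lists of these sizes would share 0.77 rises and 0.018 falls, and lists of these sizes, taken by smallest p from simulated delays without effect that shared the no-delay arrays, had a mean of 16.2 rises (at most 24) and 1.36 falls (at most 3) in common over 50 runs. The 40 shared rises exceed this, and the 3 shared falls do not. The simulation gave all arrays the same spread and held no correlation between genes. Across genes, which are not independent replicates, the changes at 2 h and 4 h correlated with r = 0.84 (covariance 0.061), against 0.50 (covariance 0.016) simulated from shared arrays alone. With 3 no-delay arrays these could not be divided between the comparisons, so part of the excess may come from them. The rise that was not called at 4 h was TRMT2B (0.88 ± 0.12 at 2 h, 0.21 ± 0.12 at 4 h). Among the 41 genes, 39 were higher at 4 h than at 2 h, by a median of 0.53, with 0.46, 0.49 and 0.47 in the 3 donors.

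Tested directly in the fit to all arrays, no gene passed for 4 h against 2 h (limma, smallest adjusted p = 0.9996). An unadjusted p under 0.05 was reached by 684, fewer than 5% of the genes tested. The spread was taken from all arrays, including the no-delay array of donor 1, which lies outside this contrast and raised the residual SD. The absence of calls is therefore not evidence of no change. The smallest p among rises belonged to JUN (1.26 ± 0.18), HBEGF (0.86 ± 0.14) and NAMPT (0.95 ± 0.16), and among falls to TRMT2B (-0.67 ± 0.12), APOL6 (-1.30 ± 0.23) and POLH (-0.64 ± 0.12), each in 3 of 3 donors and none past the threshold. POLH was called at 4 h against no delay (-0.65 ± 0.12) but read 0.07 with the probe set chosen by type and ID. A fit to the 6 arrays of these delays alone called 45 genes, 41 up and 4 down. The count was 35 without the no-delay array of donor 1, 24 without all of that donor's arrays and 2 without the 4 h array of that donor. No gene departed from a straight line over 0, 2 and 4 h (limma, smallest adjusted p = 0.57; 296 at an unadjusted p under 0.05, also fewer than 5%), and 6 did without the no-delay array of donor 1.

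Taking the 3 times at once, 192 genes differed between delays by limma's moderated F. The count ranged from 15 to 163 without 1 array other than the no-delay array of donor 1, and was 1082 without that array. As a description, delay accounted for a median of 22.4% of a gene's variance, the donor for 21.3% and the residual for 47.5%. Delay and donor each had 2 of the 8 degrees of freedom, or 25%, and the residual 50%. These are the mean shares that noise would give, so the medians cannot be set against them directly. Of the sum of squares over all genes, delay held 30.5%, the donor 32.2% and the residual 37.3%, a sum in which variable genes weigh most. The share of delay exceeded that of the donor in 51.4% of genes. Probe sets were chosen for a large SD within donors, which tilts this comparison towards delay, so nothing is concluded from it.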

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

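The tests of further probe sets, of the spread of donor 1 and of marker lists without 1 array were chosen after the results were seen. Planned before them were the lists for 4 h against 2 h and the tests of carried-over cells, array shifts, RNA breakdown and cell loss. The rearrangements of delays with the donor block were planned too. The calls among probe sets outside the comparisons and the splits without the block were not among the planned tests. With camera's preset correlation, 13 lists differed between 4 h and 2 h. Median changes from 2 h to 4 h were 0.31 for RNA splicing factors, 0.29 for immediate early genes, 0.22 for NF-kB targets, 0.19 for cAMP and CREB genes, 0.15 for hypoxia targets, 0.14 for glucocorticoid responsive genes, 0.14 for circadian clock genes, 0.14 for cytokines, 0.070 for p53 targets, 0.047 for the unfolded protein response and 0.046 for oxidative phosphorylation. T cell and B cell markers were lower at 4 h than at 2 h, by medians of -0.10 and -0.11. None of the 13 passed camera with an estimated correlation (lowest adjusted p = 0.12), and no single gene passed for 4 h against 2 h in the fit to all arrays.

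Probe sets outside the comparisons also held calls. Of 1801 probe sets with several symbols, 40 were called for 4 h against no delay (32 up, 8 down), which is 2.22%. Of 11721 with no symbol here, 10 were called (9 up, 1 down), which is 0.085%. Of 45 bacterial and phage control probe sets, 0 were called, and the largest rise among them was 0.24. Adjusted p-values were computed within each of these sets.

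The rise of 370 genes at 4 h was set against 4 technical explanations. Granulocytes or platelets carried over would bring their own transcripts, but the 30 neutrophil markers changed by a median of -0.030 (95% bootstrap interval over markers -0.11 to 0.04) and the 28 platelet markers by -0.17 (-0.28 to -0.11), against 1.01 for the called rises. Without the no-delay array of donor 1 the neutrophil median turned to 0.10 (0.04 to 0.19) and the platelet median was -0.40 (-0.46 to -0.29). Both were still below the bound of 0.25, which comes from the called rises of the fit to all arrays and was not set anew. The intervals resample markers and do not measure the spread between donors. Donor medians were -0.33, 0.15 and 0.17 for neutrophil and 0.29, -0.39 and -0.51 for platelet markers. The platelet median of donor 1 thus passed the bound of 0.25, while every donor median lay below 1.01. Cross-hybridization or a transcript variant seen by 1 probe set would leave further probe sets to rise no more often than those of genes not called. Of 281 called rises with further probe sets, 63.7% had at least 1 that rose at an unadjusted p under 0.05, against 15.3% expected. This argues against the explanation for the shared rises as a set, not for each of them. The expected share treats probe sets of a gene as independent, although they were read on the same arrays. The explanation stays open for the 102 without a further risen probe set and the 89 with a single probe set. In 6.76% of the 281 a further probe set fell, and the median change of the further probe sets was 0.27, against 1.01 for the called rises. A shift of whole arrays left by the normalization stays open too: centring left 372 called rises but moved the median of all genes by only 0.014, so it decides nothing. Other differences that run with delay, such as the order of array runs, and a response of the cells to the wait were not tested.

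The fall of 121 genes at 4 h was set against RNA breakdown and against a loss of monocytes or NK cells. The signal of 3 prime over 5 prime probe sets changed by 0.0072 (± 0.10 SE over 3 donors; 0.22, -0.10 and -0.10 in donors 1, 2 and 3). This is below 0.5, a bound chosen beforehand and not calibrated on degraded RNA. The measure rests on beta-actin and GAPDH, so breakdown limited to other transcripts was not tested. The 26 monocyte markers changed by a median of 0.16 (-0.09 to 0.34) and the 19 NK cell markers by 0.074 (-0.12 to 0.12), against -0.83 for the called falls. With the no-delay array of donor 1 left out they were 0.12 (-0.10 to 0.23) and -0.05 (-0.17 to 0.06). The NK median thus turned below 0, still above the bound of -0.21. That bound comes from the called falls of the fit to all arrays and was not set anew. These intervals are over markers and do not measure the spread between donors. Donor medians were 0.07, 0.11 and 0.03 for monocyte and 0.23, -0.13 and -0.05 for NK cell markers, all above that bound. A loss of either cell type as a whole is argued against, while a loss of a subset, such as cells with high CX3CR1 or CCR2, was not tested.

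The residual spread, after donor and delay are fitted, came largely from 1 array. Without the no-delay array of donor 1 the median residual SD over genes was 0.13, near the 0.12 without all arrays of that donor; the lowest value without any other single array was 0.18. Less intact RNA in that sample would lower the 3 prime over 5 prime signal from no delay to 4 h in donor 1. There it changed by 0.22, above 0 in both transcripts. From no delay to 2 h it changed by 0.028, with beta-actin at 0.057 and GAPDH at -0.0005. The value at 4 h also depends on the 4 h array, so it does not settle the question for the no-delay sample. Whether the array departs for a technical reason or because that sample differed cannot be decided with 1 sample per donor and delay. The 491 calls at 4 h were all among the 1349 made without it, and the split between rises and falls rests on it.

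Counts were set against other arrangements of the samples. With the donor block, the 3 delays can be assigned within donors in 36 ways. Only 1 gave as many genes by the moderated F as the real one, namely the real one with 192, and the highest other had 6. No share below 1 of 36 can be reached, so a chance arrangement is unlikely but not excluded. Without all arrays of donor 1, 2 or 3 the count by the moderated F was 949, 0 or 1. For 4 h and for 2 h against no delay the 6 arrays have only 10 splits, too few for a share under 0.05. In both, 1 split reached the real count (491 and 44), the real one, and the highest other had 0; of these 9, 3 part as many pairs of samples from 1 donor as the real split does. Without the block, 100 of the 280 splits of the 9 arrays were drawn; the real one gave 182 genes, the highest other 107, and the split by donor 231, which shows the donors as a structure of the samples.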

How the results depend on the processing

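The robust prior, the choice of probe set by type and ID, the genes at or above the median SD within donors, and the gene lists with other probe sets or without the no-delay array of donor 1 were chosen after seeing the data. The filters by brightness, the repeated quantile normalization and the intensity trend were not run, because the ratios hold no signal level; signal over background could not be assessed. The donor block is the main setting: without the block the counts were 435 at 4 h, 43 at 2 h, 0 for 4 h against 2 h, 0 off a straight line and 182 at any time, and 376 of the 491 and 30 of the 44 calls were shared. It moved no count by over 1.5 times. Counts also stayed within 1.5 times with the donor as a random effect, centring, the mean of probe sets, every probe set on its own, the robust prior, type and ID, and a minimum of 1.5-fold, but the calls were partly others: of the 491 and 44, the mean of probe sets shared 282 and 26, type and ID 311 and 27, the random effect 367 and 30, the robust prior 450 and 44 and centring 472 and 44. Centring moved the median of all genes at 4 h by 0.01.

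Array quality weights gave 1584 genes at 4 h (787 up, 797 down), 1054 at 2 h, 240 for 4 h against 2 h, 98 off a straight line and 1527 at any time; 1 of the 2 h arrays took a weight of 157 and the no-delay array of donor 1 one of 0.045, and the estimation of the weights stopped before it converged, so these counts are not relied on. Genes at or above the median SD gave 799, 124, 16, 3 and 547, with fewer genes tested and a choice that favours changes with delay. The 6 arrays of each comparison alone, with fewer degrees of freedom, gave 47 at 4 h, 4 at 2 h and 45 for 4 h against 2 h. An adjusted p of 0.1 gave 889 at 4 h and 115 at 2 h. With an array or a donor left out, counts ran from 0 to 1349 at 4 h, 0 to 611 at 2 h, 0 to 35 for 4 h against 2 h, 0 to 6 off a straight line and 0 to 1082 at any time; the highest in each came without the no-delay array of donor 1.

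Of 27 lists, 14 passed at 4 h and 14 at 2 h. With an estimated correlation 0 and 0 passed, and with fry 11 and 6. Of the lists that passed camera at 4 h, fry did not pass NRF2, oxidative phosphorylation, ribosomal and platelet (fry adjusted p = 0.12, 0.16, 0.17 and 0.35). It did pass the basophil and eosinophil list (adjusted p = 0.028), which camera did not. With a donor left out, or without the no-delay array of donor 1, 13 to 15 passed at 4 h and 5 to 13 at 2 h. Without that array the medians of 19 lists at 4 h and 22 at 2 h lay over 1.5 times apart from those of all arrays or on the other side of 0 (3 and 9 of them). The ribosomal list at 2 h turned from a median of 0.05 to -0.0088 without that array, the lowest of the leave-outs, which reached 0.082. Reversed with the probe set by type and ID, where another probe set is read and the cause was not tested, were ETNK1 (-0.12 at 4 h, -0.11 at 2 h), YIPF5 (0.04 at 4 h), POLH (0.070 at 4 h), KLF9 (-0.23 at 4 h, -0.25 at 2 h) and PER3 (-0.20 at 4 h); no other named gene changed direction in any setting where it or the alternative was called. The median share of variance by delay, 22.4%, ran from 21.5% to 24.6%.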

Other observations

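The GIMAP and chemokine receptor families were chosen after 3 GIMAP genes and 2 receptors had appeared among the largest falls, so both tests run on genes that prompted them. GIMAP genes sit in 1 cluster and encode small GTPases that act in lymphocyte survival. All 7 measured members lay below 0 at 4 h, and 4 fell: GIMAP8 (-1.49 ± 0.13), GIMAP6 (-1.23 ± 0.12), GIMAP4 (-1.19 ± 0.14) and GIMAP1 (-1.01 ± 0.14). GIMAP7 stood at -0.87 ± 0.19 (adjusted p = 0.053), GIMAP2 at -0.26 ± 0.14 and GIMAP5 at -0.11 ± 0.13. Camera gave p = 1.46e-09 with the preset correlation and p = 0.0099 with an estimated one. The members below 0 numbered 7 with centring, with the mean of probe sets and with the probe set by type and ID, and 6 without the no-delay array of donor 1. A fall of the family as a whole is a hypothesis that these values are consistent with.

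Chemokine receptors moved both ways. CX3CR1, CCR2, CXCR3 (-0.84 ± 0.14) and CXCR2 (-0.65 ± 0.11) fell and CXCR4, which lymphocytes use to follow CXCL12, rose (0.90 ± 0.15). Of 16 measured receptors 12 lay below 0, with a median of -0.14 and CCR7 at -0.03 ± 0.16. Camera gave p = 0.014 with the preset correlation and p = 0.13 with an estimated one, so a fall of the family may rest on its 4 called members. The count below 0 was 12 with centring and both other choices of probe set, and 11 without the no-delay array of donor 1.

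Several genes risen at 2 h lie outside the lists and are named after their values were seen. Examples are ZNF331 (1.41 at 2 h and 2.21 at 4 h), TUBB2A (1.49 and 2.08), BTG3 (1.20 and 1.88) and BCL10 (1.10 and 1.72). OSM, DDIT4 and DUSP5 had changed by about as much at 2 h (1.17, 0.95 and 1.23) as at 4 h (1.19, 0.95 and 1.35), while JUN stood at 0.84 at 2 h and 2.09 at 4 h. In the fit to all arrays the difference between 4 h and 2 h did not pass for any of them.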
